A study of Mus musculus with 6 samples.

How the data were processed

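The series held 6 droplet-based RNA libraries from hindbrain tumours of a mouse model of paediatric high-grade glioma that carries the H3.3K27M histone mutation, loss of ATRX and P53 function and overexpressed wild-type PDGFRA. Tumours either arose in place after in-utero electroporation of the mutations (de novo) or grew from de novo tumour cells injected into a new mouse (engrafted). There were 2 libraries of nuclei from de novo tumours, 2 of nuclei from engrafted tumours and 2 of whole cells from engrafted tumours, grouped by the sample titles and descriptions. The labels' protocols describe microdissection of fluorescent tumour and of stroma, papain digestion and the 10x Chromium chemistry that reads the 3′ end of transcripts, and they do not say which part each library held. The protocols also describe antibody treatment of mice and immunodeficient hosts without tying either to a library, and all 6 libraries are labelled as female C57BL/6J. Nothing in the labels said that the libraries of a group came from separate animals, so p-values measured only the spread between these libraries, which may be technical. For the de novo libraries, sex-linked RNA argues against a shared animal. Replicates 1 and 2 had 391.0 and 6.42 CPM of Y-linked genes and 0.414 and 1280 CPM of Xist. For the engrafted groups the question stays open.

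The authors deposited a matrix of raw UMI counts for each library, that is, unnormalised counts of unique molecular identifiers per gene and barcode, per the file headers and the values. Cell Ranger 3.0.1 and the genome build mm10 are listed for all libraries in the submitters' processing notes, and Cell Ranger 6.1.1 is listed in addition for the engrafted nuclei. Per the file headers, the matrix of engrafted nuclei replicate 1 was written by version 6.1.1 and the other 5 by version 3.1.0. Engrafted nuclei replicate 1 also shared at most 1 barcode sequence with any other library, while each pair of the others shared 25 to 134. It thus differed technically from its replicate, for a reason that the labels do not give. Whether intronic reads were counted is not given in the sources used here. Each matrix held 27998 mouse genes and 13 features for parts of the electroporated constructs, such as GFP, the Akaluc luciferase and tagged H3.3. Construct features were reported as values and left out of the tests.

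Depth differed between preparations. The libraries held 24308 and 20453 barcodes with 91882342 and 54058626 UMIs in de novo nuclei, 10676 and 15264 barcodes with 72584205 and 50423914 UMIs in engrafted nuclei, and 9511 and 10888 barcodes with 179894726 and 151774071 UMIs in engrafted cells, replicates 1 and 2 in turn. Barcodes with fewer than 500 genes were left out, as were nuclei with over 5% and cells with over 15% mitochondrial UMIs. Doublets were scored against simulated doublets within each library. Of the doublets expected at 0.8% per 1000 barcodes, only the part assumed to join unlike cells was removed, highest scores first. That took 2353, 1673, 369, 930, 279 and 365 barcodes in the same order (9.7%, 8.18%, 3.84%, 6.1%, 3.34% and 3.82%). This left 21901 and 18779 de novo nuclei, 9233 and 14316 engrafted nuclei, and 8072 and 9194 engrafted cells.

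No cell annotation was used from outside, so each library was clustered on its own (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1) and clusters were named from 154 markers of 16 classes fixed before the data were examined, as were the main tests, the gene lists and the rule for named genes. The scoring rule that turned markers into names was set after the clusters were seen and was revised several times before any comparison between groups was run, and it decides which classes reached the minimum of 50 barcodes per library. A class scored the mean log2 fold of its markers, with 10 CPM added, over the cluster at percentile 25 of the library. It was eligible with at least 3 markers over 1.5-fold that made up a share above 0.6 of its markers. A share of at least 1/3 was enough where 1 marker was among the cluster's 200 leading genes. The eligible class with the highest score gave the name. Where another eligible class of its family had more markers among the cluster's 10 leading genes, that class took the name instead. Microglia-like, macrophage-like, dendritic-like and neutrophil-like classes formed the myeloid family, so this step could decide between their names. Immune clusters were pooled, clustered again and given immune names only. A cluster stayed unnamed where mitochondrial, ribosomal or haemoglobin genes led it, where its median UMI count was low and none of the class's markers led it, where markers of another class led it, or where its leading genes were shared mainly with clusters of the other lineage in other libraries. The word "like" marks each name as resting on markers alone, and a difference from any published annotation can come from these rebuilt names.

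Raw counts were summed per library and class, and the sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, TMM scaling, filterByExpr) in one fit of all libraries holding at least 50 barcodes of the class, with Benjamini-Hochberg adjustment at 0.05. All 6 libraries entered except in the macrophage-like class, where de novo nuclei replicate 2 held none and 5 entered. The engrafted cells therefore contributed to the estimate of spread in the comparisons of nuclei. All adjusted p-values of genes below are from this test. Expression per library is given as CPM scaled by the TMM factors for named genes of a comparison, and as unscaled CPM of a class or library where classes or constructs are described. The 24 fixed gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with the correlation estimated from the data, and the adjusted p-values of lists are from camera. Shares of barcodes were compared with a two-sided exact permutation test of libraries, for which 2 against 2 cannot give a p below 0.333. Intervals of shares are 95% Wilson intervals, and a share or level of 0 was given the limit that 3 counts allow, taken over the group for gene levels and for class shares of a group. Intervals and limits cover counting error only. Clusters were named whole, so a class share of 0 can come from the naming, and its limit does not bound the true share.

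Genes were named by rule: in each comparison, up to 10 in each direction with the largest fold among those past the threshold with non-overlapping libraries, at least 20 CPM in the higher group and at least 1/5 of the level of the highest class of that group, a guard against free RNA in the droplets; the up to 4 members of each fixed list with the smallest adjusted p, passing or not; and the genes of the tumour model. Mitochondrial, ribosomal and unnamed genes were left out of the first part. Planned comparisons of microglia-like nuclei, of macrophage-like nuclei between tumour types, of microglia-like barcodes between preparations, and the test of whether 2 classes responded differently were not run, since a library needed for each held under 50 barcodes of the class. Comparisons of T/NK-like nuclei and of macrophage-like and microglia-like nuclei pooled were added after class sizes were known, as were list tests between preparations.

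Alternatives were DESeq2 1.42.0, its size factors inside edgeR, no filter on low counts, a fit of the 4 compared libraries only, doublets kept, at least 1000 genes per barcode, Leiden resolution 2, sums thinned to equal depth, genes under the free RNA guard left out, a replicate block and each library left out in turn. The tests were run first on simulated counts with 200 changed genes and on counts with none. Replicates of a group differed far beyond sampling noise: chi-square over its degrees of freedom was 395 in de novo nuclei, 671 in engrafted nuclei and 144 in engrafted cells, so each library was counted as 1 replicate. Gene positions are from the GENCODE vM21 annotation of GRCm38. Computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and R 4.3.3.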

Results

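The libraries described the cells of a mouse high-grade glioma model and of the brain around it, in tumours that arose in place and in tumours grown from transplanted cells. De novo nuclei gave 21901 and 18779 barcodes for analysis, engrafted nuclei 9233 and 14316, and engrafted cells 8072 and 9194. Median depth before filtering was 2368 and 2110 UMIs per barcode in de novo nuclei, 4669.5 and 2719.5 in engrafted nuclei, and 14639 and 10804 in engrafted cells, so levels in whole cells were the most precisely measured. The design implies a comparison of engrafted with de novo tumours among nuclei and a comparison of whole cells with nuclei among engrafted tumours. The series title places its interest in the immune compartment and its myeloid cells. Both contrasts are between groups of 2 libraries. De novo replicate 1, labelled female, had 391.0 CPM of 4 Y-linked genes and 0.414 CPM of Xist, the RNA of the inactive X chromosome, against 6.42 and 1280 CPM in de novo replicate 2 and Y-linked RNA of at most 7.99 CPM in the engrafted libraries.

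The genes of the model were examined first, in barcodes resembling oligodendrocyte precursor cells (OPC-like). Pdgfra, the growth factor receptor overexpressed in the model, stood at 613 and 67.0 CPM in OPC-like de novo nuclei, 316 and 134 in engrafted nuclei, and 302 and 594 in engrafted cells. Akaluc, a luciferase carried by the constructs, stood at 2.99 and 0.443 CPM in OPC-like de novo nuclei against 37.8 and 56.5 in engrafted nuclei and 113 and 208 in engrafted cells. The tagged H3.3 feature followed the same order, at 0 and 0.554, 27.8 and 40.6, and 30.8 and 63.2 CPM. GFP did not, with 18.9 and 100.0 CPM in OPC-like de novo nuclei, 3.41 and 1.67 in engrafted nuclei, and 9.11 and 17.3 in engrafted cells. In de novo replicate 2 GFP was also at 66.8 CPM in T/NK-like nuclei, so the constructs did not separate tumour from host OPC-like nuclei there. Between nuclei groups the log2 fold change of engrafted over de novo was −0.61 ± 0.98 (SE) for Pdgfra, 0.77 ± 0.45 for Atrx and 1.00 ± 0.61 for H3f3a, with adjusted p of 0.747, 0.329 and 0.345. Trp53 rose by 1.66 ± 0.31 (adjusted p = 0.0397), from 15.6 ± 3.23 to 50.5 ± 9.96 CPM (SD, n = 2). Reads at the 3′ end do not cover the edited or silenced sites, so none of these levels checks the loss of function.

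More nuclei of engrafted tumours were named OPC-like and macrophage-like, and more nuclei of de novo tumours neuron-like, astrocyte-like and microglia-like. OPC-like nuclei made up 42.8% ± 3.53 (SD, n = 2) of engrafted and 10.0% ± 11.8 of de novo nuclei. Nuclei resembling committed oligodendrocyte precursors were 17.6% ± 11.3 of engrafted nuclei, and none of the de novo nuclei were given that name. With 3 nuclei set in place of 0 the share was 2380-fold higher. Clusters were named whole, so that fold is not a lower bound. Neuron-like nuclei were 9.82% ± 11.5 of engrafted and 47.9% ± 12.8 of de novo nuclei. Astrocyte-like nuclei were 1.86% ± 0.142 and 6.80% ± 2.35 in the same order, and oligodendrocyte-like nuclei 3.16% ± 3.91 and 12.9% ± 10.0. T/NK-like nuclei were 3.32% ± 0.402 and 1.96% ± 0.879. The 2 de novo libraries were unlike each other: OPC-like nuclei were 1.64% of replicate 1 (Wilson interval 1.48% to 1.82%) and 18.4% of replicate 2 (17.8% to 18.9%). The exact permutation test gave p = 0.333 for each of these classes except oligodendrocyte-like (p = 0.667), and 0.333 is the smallest p that 2 against 2 libraries allow. How much tumour and stroma was dissected into each library sets these shares too, and without de novo replicate 2 the log2 ratio of OPC-like shares moved from 2.10 to 4.70. Unnamed clusters held 16.3% ± 6.61 of engrafted and 12.9% ± 12.2 of de novo nuclei, and among them were 1780 nuclei of engrafted replicate 2 (12.4%) that scored as macrophage-like but were led by mitochondrial or ribosomal genes.

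**Figure D1:**
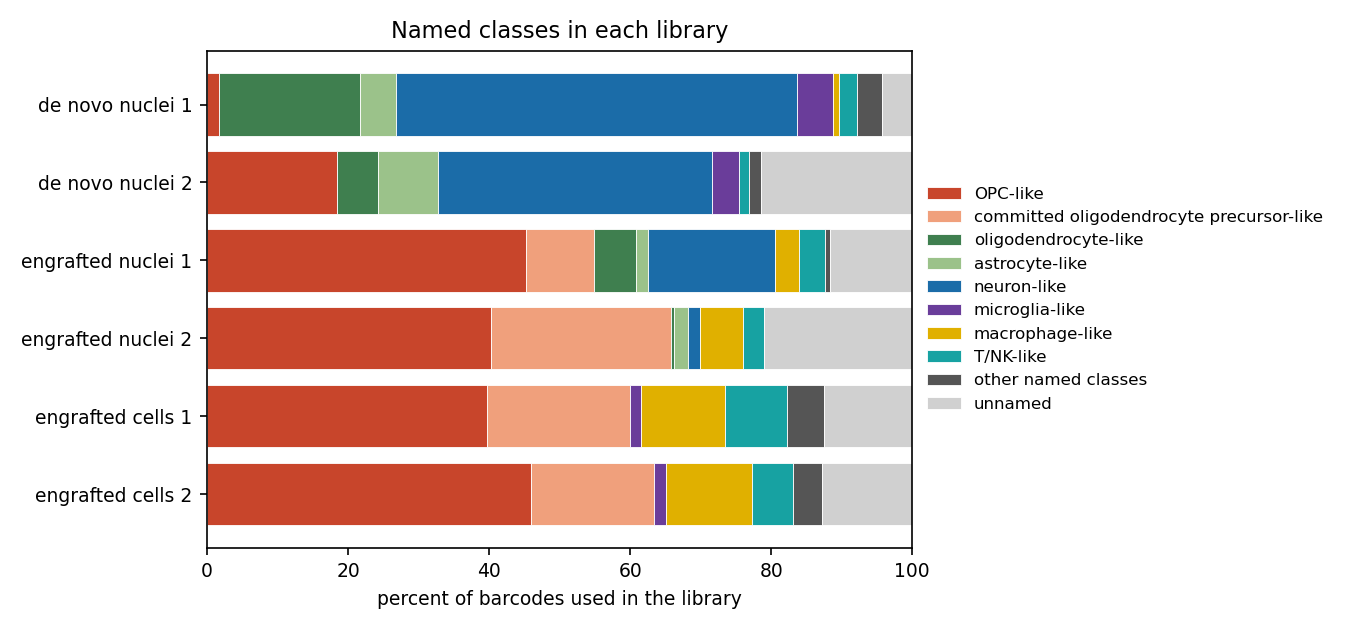
Percent of barcodes in each named class (horizontal axis, stacked to 100) for each of the 6 libraries (vertical axis). Neuron-like nuclei are the widest segment of both de novo libraries, at 56.9% and 38.9%, and OPC-like nuclei fill 42.8% of engrafted nuclei on average.

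The named myeloid nuclei were mainly microglia-like in de novo tumours and mainly macrophage-like in engrafted ones. Microglia-like nuclei, marked by genes such as P2ry12 and Tmem119, were 4.46% ± 0.816 of de novo nuclei and were not named in either engrafted nuclei library. With 3 nuclei set in place of 0 the share was 350-fold lower. Clusters were named whole, so this is not a lower bound. Macrophage-like nuclei were 4.84% ± 1.83 of engrafted and 0.406% ± 0.575 of de novo nuclei, 11.9-fold apart (log2 ratio 3.57, and 2.57 to 8.24 with a library left out). Those of de novo nuclei were all in replicate 1. Of the macrophage-like and microglia-like nuclei combined, the macrophage-like share was 100.0% in both engrafted libraries (327 of 327 and 878 of 878 nuclei). It was 13.9% (Wilson interval 12.1% to 15.9%) and 0.0% (0 of 730 nuclei) in the de novo libraries. By counting error alone, 0 of 730 allows up to 0.411%. The mean difference was 93.1 percentage points, with an exact permutation p of 0.333. Whole cells of engrafted tumours held both classes, 88.0% and 87.4% macrophage-like. Doublets kept or a finer clustering at resolution 2 named microglia-like nuclei in engrafted replicate 1, bringing the log2 ratio of microglia-like shares from −8.45 to −2.90 and −2.72. The contrast behind the names was weak in all nuclei: the median fold of macrophage markers over their level in T/NK-like barcodes was 3.12 and 1.70 in engrafted nuclei. It was 2.13 and 1.07 in de novo nuclei, and 22.8 and 18.0 in engrafted cells. That of microglia markers was 5.39 and 2.02 in de novo nuclei, 1.29 and 1.79 in engrafted nuclei, and 15.3 and 9.89 in engrafted cells. In engrafted nuclei replicate 2 microglia markers thus stood no lower than macrophage markers, although every named myeloid nucleus there was macrophage-like. Summed over all barcodes, named or not, 11 microglia markers kept a median of 0.735 of their de novo level in engrafted nuclei, with 0.161 for Crybb1, 0.428 for P2ry12 and 1.29 for Tmem119. The fall in named microglia-like nuclei was not matched by an equal fall of marker RNA, part of which other cells can carry. Macrophage markers over all barcodes had a median ratio of 0.93 to 2.45 between pairs of an engrafted and a de novo nuclei library. Single macrophage markers went both ways. The ratio of mean engrafted to mean de novo level was 4.99 for Tgfbi, 4.43 for Ccr2 and 3.72 for Ms4a7. It was 0.188 for Cd163, 0.215 for F13a1 and 0.424 for Pf4. Some macrophage markers thus rose and others fell, and the 11.9-fold rise in named macrophage-like nuclei was not matched by an equal rise of marker RNA.

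**Figure D2:**
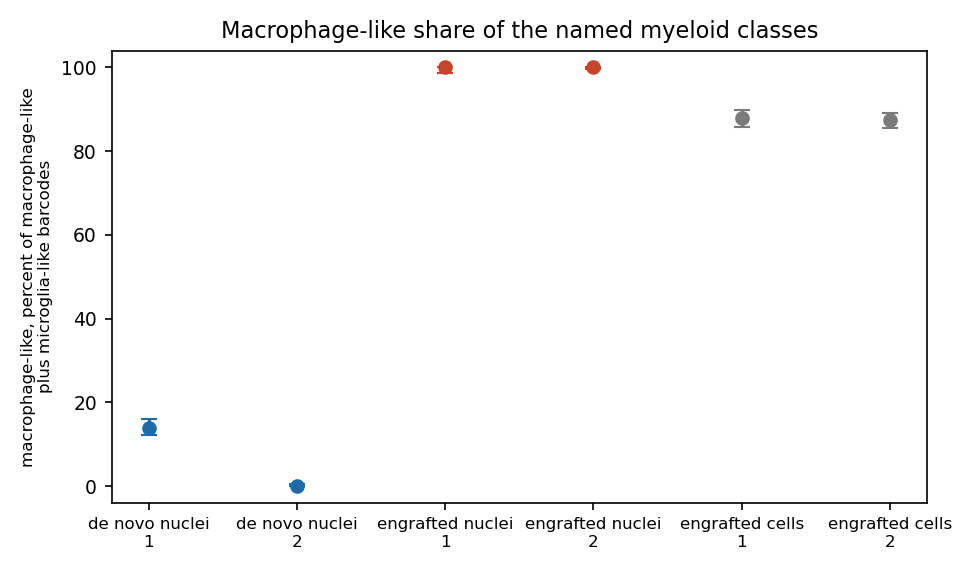
Macrophage-like barcodes as a percent of macrophage-like plus microglia-like barcodes (vertical axis) in each library (horizontal axis), with 95% Wilson intervals for counting error. The de novo libraries lie at 13.9% and 0.0%, the engrafted nuclei at 100.0% and the engrafted cells at 88.0% and 87.4%.

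Within OPC-like nuclei, the genes with the largest folds upward in engrafted tumours included Dlx6os1, Fendrr and Dlx6, which had no UMI in de novo OPC-like nuclei. Dlx6os1 (ENSMUSG00000090063), a long noncoding RNA of the Dlx5 and Dlx6 homeobox locus, stood at 91.2 ± 4.99 CPM in engrafted OPC-like nuclei (SD, n = 2) with no UMI in de novo ones, at least 415-fold higher (adjusted p = 0.022). Dlx6, the homeobox gene it overlaps, was at least 97.7-fold higher (adjusted p = 0.0228), and since the counting of strand is not given in the sources used here, the levels of this pair are uncertain. Fendrr, a long noncoding RNA of mesoderm development, was at least 343-fold higher (adjusted p = 0.022). Lmx1b, a homeobox gene of hindbrain patterning, rose by 6.83 ± 0.89 on the log2 scale (SE, adjusted p = 0.0256), and the matrix genes Hapln1, Col2a1 and Col4a1 rose by 6.25 ± 1.05, 4.89 ± 0.57 and 2.01 ± 0.30 (adjusted p = 0.0341, 0.0228 and 0.0291). Of 18388 genes tested, 954 passed, 371 higher and 583 lower in engrafted nuclei. A fit of the 4 nuclei libraries alone passed none with edgeR (3357 at an unadjusted p under 0.05), while DESeq2 on all 6 passed 3079, and edgeR passed 88 without engrafted replicate 2, 268 without engrafted replicate 1 and 358 without de novo replicate 2. DESeq2 was the looser test: on simulated counts with no gene changed it called up to 58 genes, against 0 with edgeR. With 200 genes changed, 19.75% of edgeR's and 25.18% of DESeq2's calls were false, both above the threshold of 0.05. Of genes changed 4-fold, edgeR recovered 19.4% and DESeq2 50.7%. The OPC-like class was held by 1 cluster in de novo replicate 1, led by Vcan, Sox6 and Pdgfra, and by 1 cluster with 98.6% of it in de novo replicate 2, led by Hmga2, Fbn2 and Tnc. In engrafted replicate 1 its clusters were led by Tnr and Bcas1 (38.3%), Top2a and Kif11 (30.4%), Ciita and Iigp1 (22.4%) and Mx1 and Rsad2 (7.5%), and in replicate 2 by Sgcd and Chrm3 (38.3%), Neil3 and Kif23 (24.2%), Megf11 and Gria2 (18.6%) and Mx1 and Ifi44 (17.5%). De novo replicate 1 also differed from the other 3 nuclei libraries in Y-linked RNA. Construct features did not show that the de novo OPC-like nuclei were tumour. Changes in this class may thus partly set tumour against host nuclei, which was not tested.

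**Figure D3:**
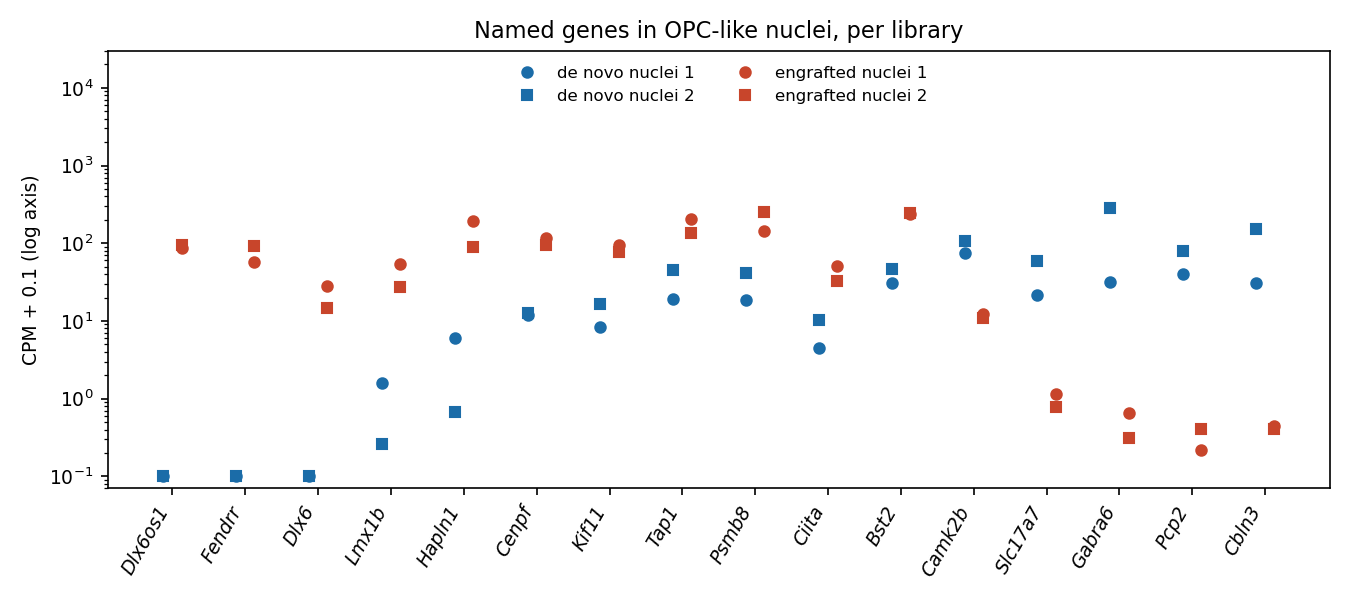
TMM-scaled CPM plus 0.1 (vertical axis, log scale) of 16 named genes (horizontal axis) in OPC-like nuclei, 1 point per library, de novo in blue and engrafted in red. Genes from Dlx6os1 to Bst2 lie higher in both engrafted libraries, and genes from Camk2b to Cbln3 lie lower.

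Cell division and antigen presentation genes rose in engrafted OPC-like nuclei, and as lists they also rose in T/NK-like and pooled myeloid nuclei. The median log2 fold change in that order was 2.20, 1.96 and 2.91 for cell cycle and 1.82, 0.80 and 1.43 for MHC class I. Whether free RNA of other cells carried part of this was not tested. In the OPC-like class the rise may also partly set engrafted tumour against de novo host nuclei, which was not tested either. Of 28 cell cycle genes, 10 rose and 25 did so adjusted over the list alone, among them Cenpf, a kinetochore protein, from 12.2 ± 0.545 to 105 ± 13.3 CPM (log2 fold change 3.1 ± 0.36), the spindle motor Kif11 (2.72 ± 0.43), the replication factor Mcm5 (2.43 ± 0.39) and the chromatin remodeller Hells (2.32 ± 0.36). Clusters led by mitotic genes held 30.4% and 24.2% of the engrafted OPC-like nuclei. Of 12 MHC class I genes 3 rose, and 11 adjusted over the list alone: the peptide transporters Tap1 (2.39 ± 0.49) and Tap2 (2.07 ± 0.43) and the immunoproteasome subunit Psmb8 (2.70 ± 0.57). Of 9 MHC class II genes 2 rose, H2-DMb1 (2.79 ± 0.36) and the class II transactivator Ciita (2.35 ± 0.49); adjusted over the list alone 5 rose and 1 fell. Of 20 interferon response genes 2 rose, and 5 adjusted over the list alone, among them Bst2 (2.62 ± 0.49). The lists passed as groups, with camera's adjusted p of 2.41e-15 for cell cycle, 2.72e-07 for MHC class I, 6.32e-05 for interferon response and 0.0123 for MHC class II. None held with an estimated correlation: cell cycle and both MHC lists then had an adjusted p = 0.539 with an estimated correlation, and interferon response an adjusted p = 0.618. MHC class II also lost its call without de novo replicate 2 (adjusted p = 0.0588), and under 3 of its genes were left once genes that free RNA could carry were set aside.

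Neuronal genes were lower in engrafted OPC-like nuclei, but Gabra6, Pcp2 and Cbln3, with some of the largest folds, were lower in OPC-like than in T/NK-like nuclei of both de novo libraries. The granule cell receptor subunit Gabra6 fell from 159 ± 180 to 0.386 ± 0.242 CPM (log2 fold change −8.66 ± 1.34, adjusted p = 0.0312), and Pcp2, a Purkinje cell gene, fell by 8.16 ± 0.67 on the log2 scale (adjusted p = 0.022). Cbln3 fell by 8.14 ± 0.92 (adjusted p = 0.0228), and Neurod2 had 1 count in engrafted against 451 in de novo nuclei, a ratio of 1780 (counting interval 320 to 70400). In de novo replicates 1 and 2, Gabra6 stood at 42.9 and 390 CPM in OPC-like and at 68.0 and 537 CPM in T/NK-like nuclei, and Pcp2 at 53.8 and 107 against 79.7 and 165. Across classes of de novo replicate 1 Gabra6 ranged from 26.5 CPM in macrophage-like to 124 in neuron-like nuclei. Of 20 neuronal and synaptic genes 12 fell, and 17 adjusted over the list alone (camera's adjusted p = 4.74e-16). They included Camk2b (log2 fold change −3.00 ± 0.31) and the glutamate transporter Slc17a7 (−5.57 ± 0.65). Of 18 astrocyte genes 3 fell, and 9 adjusted over the list alone (adjusted p = 4.47e-05), with the bicarbonate transporter Slc4a4 down by 4.73 ± 0.74. Of 14 oligodendrocyte maturation genes 1 fell, St18 (−2.61 ± 0.50), and 4 adjusted over the list alone (adjusted p = 0.0123). With an estimated correlation these lists had an adjusted p = 0.539, adjusted p = 0.539 and adjusted p = 0.691 in turn. Under the free RNA guard the neuronal list passed on 14 genes (adjusted p = 4.59e-15), while the astrocyte list had an adjusted p of 0.264 and the maturation list 0.999. The guard cannot set aside RNA spread evenly over the classes, so that pass does not speak against free RNA. In T/NK-like nuclei the guard left 17 neuronal genes. The maturation list also lost its call without de novo replicate 1 (adjusted p = 0.897) or engrafted replicate 2 (adjusted p = 0.177). The OPC programme, 10 of whose 16 tested genes are class markers, did not pass (adjusted p = 0.804), with a negative median (−0.24) and mean (−0.11) and a test direction upward. It was higher in engrafted nuclei without de novo replicate 1 (adjusted p = 4.54e-07) and lower without de novo replicate 2 (adjusted p = 0.000237), and 1 member fell, the adhesion gene Cntn1 (−2.27 ± 0.44, adjusted p = 0.0425).

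**Figure D4:**
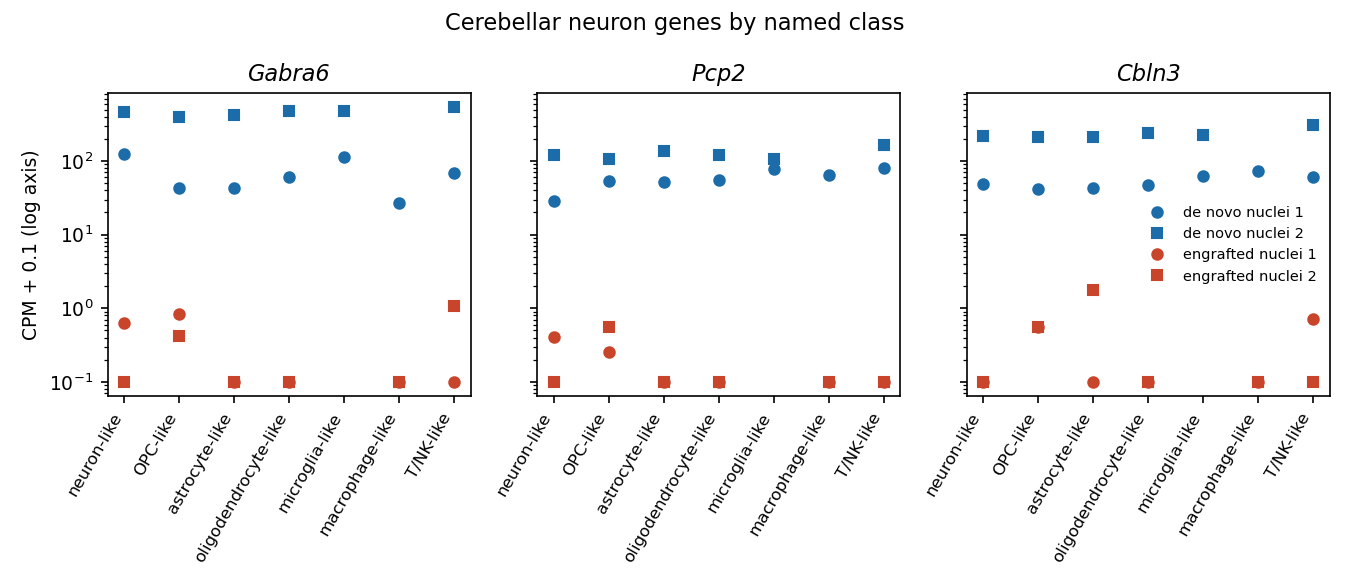
Unscaled CPM plus 0.1 (vertical axis, log scale) of Gabra6, Pcp2 and Cbln3 in each named class (horizontal axis) of the 4 nuclei libraries, de novo in blue and engrafted in red, circles for replicate 1 and squares for replicate 2. Cbln3 in de novo replicate 2 lies at 209 CPM in OPC-like, 305 in T/NK-like and 218 in neuron-like nuclei, while Gabra6 in de novo replicate 1 spans 26.5 to 124 CPM.

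Between preparations of engrafted tumours, OPC-like whole cells had far more RNA of immediate early and hypoxia genes than OPC-like nuclei, and less of neuronal genes. All 19 genes of the dissociation and immediate early list rose in cells, including Fos, from 21.7 ± 8.95 to 1910 ± 270 CPM (log2 fold change 6.46 ± 0.54, adjusted p = 0.000708), Fosb (7.91 ± 0.71) and Jund (5.31 ± 0.43). Of 16 hypoxia genes 15 rose, among them Ndrg1 (5.74 ± 0.48) and the lactate dehydrogenase gene Ldha (4.95 ± 0.51). The class was made up differently in the preparations: a cluster led by Ndrg1 held 19.0% and 17.8% of OPC-like cells. No OPC-like cluster of engrafted nuclei had Ndrg1 among its 10 leading genes. Clusters led by cell cycle genes held 33.8%, 19.6% and 16.2% of OPC-like cells of replicate 1 and 20.4%, 14.0% and 9.6% of those of replicate 2, against 30.4% and 24.2% of the nuclei. A further 3.4% of the OPC-like cells of replicate 2 lay in a cluster led by both Cenpf and Ndrg1. Whether the rise of cell cycle and hypoxia genes came from which clusters made up the class was not tested. The hypoxia list also rose in macrophage-like cells over nuclei, with 10 of 15 genes up and 1 down. Camera's adjusted p there was 0.00163, and 0.233 with an estimated correlation. A further 944 and 1150 cells and 441 and 0 nuclei that scored as OPC-like stayed unnamed. The lists for cell cycle (21 of 28 genes), MHC class II (7 of 9), MHC class I (10 up and 1 down of 12), the mesenchymal programme (14 of 20, with Vim at 4.2 ± 0.54), inflammatory cytokines (10 of 15) and p53 targets (9 of 15) also rose, and 14 of 20 neuronal and synaptic genes fell, including the glutamate receptor gene Gria2 (−6.40 ± 0.58). Adjusted over the list alone the counts were 19, 15, 23, 8, 10 up and 1 down, 14, 10, 9 and 14 in the same order. Camera's adjusted p in that order was 3.77e-11, 8.85e-06, 1.14e-05, 0.000396, 0.00173, 0.00424, 0.0131, 0.0238 and 0.000886, and none held with an estimated correlation, where the smallest was an adjusted p = 0.269. Without genes that free RNA could carry, p53 targets had an adjusted p of 0.215, and MHC class II, mesenchymal, cytokine and neuronal lists had too few genes left to test. The OPC programme did not pass (adjusted p = 0.184), although 7 of its 16 genes fell, 5 adjusted over the list alone, with Megf11 at −5.98 ± 0.55, and 10 of the 16 are class markers. The median log2 fold change of all genes was −0.08 with TMM and −0.24 with DESeq2's size factors, small beside these folds.

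Several genes were abundant in OPC-like cells and had no UMI in OPC-like nuclei. Cox4i1 (chromosome 8, 120668222 to 120674207, plus strand), a subunit of cytochrome c oxidase, stood at 3480 ± 212 CPM in cells and 0 in nuclei, at least 87600-fold higher (adjusted p = 0.00072). Chchd2 (chromosome 5, 129881156 to 129887470, minus strand), Ndufa13 (chromosome 8, 69894180 to 69902558, minus strand) and the tubulin gene Tubb3 (chromosome 8, 123411424 to 123422015, plus strand) were at least 63300-fold, 28500-fold and 18000-fold higher. In the other direction Epo was at least 2290-fold lower in cells than in nuclei (adjusted p = 0.000991). Each of these genes overlaps another annotated gene on its strand, so their counts are uncertain. Of 18388 genes tested 10216 passed, 5245 higher and 4971 lower in cells, and 5970 and 6080 passed without engrafted cells replicate 1 and 2. The comparison holds everything that differed between these libraries, including depth, and 5822 genes passed when all sums were thinned to equal depth.

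Macrophage-like barcodes differed between preparations in the same immediate early genes and in cytokine and antigen presentation genes. Fosb rose by 7.40 ± 0.49 on the log2 scale in cells, and all 18 immediate early genes tested rose (camera's adjusted p = 6.34e-15; adjusted p = 0.233 with an estimated correlation). Of 17 inflammatory cytokine genes 14 rose, among them Il1b, from 21.8 ± 4.17 to 1590 ± 251 CPM (6.19 ± 0.55, adjusted p = 0.00475), and Osm (5.54 ± 0.47). Of 18 genes of disease-associated microglia 14 rose, with the signalling pair Tyrobp (6.13 ± 0.66) and Trem2 (5.82 ± 0.52), and of 9 MHC class II genes 8 rose, with H2-Eb1 at 5.06 ± 0.75 (adjusted p = 0.00742). The adjusted p was 8.73e-11, 5.35e-07 and 1.22e-06 for these lists, each with an adjusted p = 0.233 with an estimated correlation, and the counts adjusted over the list alone were equal to those over all genes. Other lists rose as well, among them homeostatic microglia (8 of 12 genes, camera's adjusted p = 0.00147). The mesenchymal programme had 12 genes up and 1 down of 19 (adjusted p = 0.00122). With an estimated correlation these 2 lists had an adjusted p of 0.233 and 0.273. Irf8 (chromosome 8, 120736358 to 120756694, plus strand), a transcription factor of macrophages and microglia, had 661 ± 56.4 CPM in cells and no UMI in nuclei, at least 653-fold higher, as did Cox4i1, at least 1880-fold. Both lie inside the span of Gm20388, an annotated gene of the same strand. OPC transcripts were lower in macrophage-like cells than in macrophage-like nuclei: 15 of 16 OPC programme genes fell (16 adjusted over the list alone, adjusted p = 7.89e-08, adjusted p = 0.233 with an estimated correlation), with Lhfpl3 at −6.72 ± 0.73, and Gria2 was at least 47.3-fold lower. In all, 5667 of 12674 genes passed, 2716 higher and 2951 lower, in a fit of 5 libraries. The count was 1723 and 1556 without engrafted cells replicate 1 and 2, and 2069 at equal depth.

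T/NK-like nuclei of engrafted tumours carried more OPC and cell cycle transcripts and fewer neuronal ones, while T cell effector genes as a group did not pass. Of 16 OPC programme genes 12 rose, and 14 adjusted over the list alone (adjusted p = 2.47e-21; adjusted p = 0.0689 with an estimated correlation), including the proteoglycan Vcan, from 9.62 ± 0.017 to 390 ± 112 CPM (5.33 ± 0.46, adjusted p = 0.0206), Sox10 (5.06 ± 0.55), Lhfpl3 (5.06 ± 0.60) and Pdgfra (3.08 ± 0.60, adjusted p = 0.0469). Col2a1 was at least 49.9-fold higher. Akaluc, the tumour construct, stood at 26.3 and 53.6 CPM in the same nuclei, against 0 and 4.45 in de novo T/NK-like nuclei. Of 28 cell cycle genes 8 rose, and 21 adjusted over the list alone (adjusted p = 8.64e-13; adjusted p = 0.503 with an estimated correlation), with Ccna2 at 64 counts against 3, a ratio of 9.74 (counting interval 3.33 to 47.2). The interferon-induced gene Bst2 rose by 2.52 ± 0.42 (adjusted p = 0.0338). Of 19 neuronal genes 3 fell, and 17 adjusted over the list alone (adjusted p = 6e-15; adjusted p = 0.218 with an estimated correlation), with Stmn2 at −6.22 ± 0.84, while Pcp2 was at least 117-fold lower and Gabra6 had 1 count against 293, a ratio of 895 (counting interval 161 to 35400). Antigen presentation lists passed here too: MHC class I (adjusted p = 0.0128), with no gene past the threshold and 4 of 12 higher adjusted over the list alone, and MHC class II (adjusted p = 0.048), with 1 of 9 higher and 4 higher and 1 lower adjusted over the list alone. Both lost their call without de novo replicate 2 (adjusted p = 0.161 and 0.179), and MHC class II also without genes that free RNA could carry (adjusted p = 0.515). Astrocyte genes were lower (3 of 17; 10 lower and 1 higher adjusted over the list alone; adjusted p = 0.000296). Growth factor response genes were higher (1 of 13; 5 adjusted over the list alone; adjusted p = 0.0264), but not without de novo replicate 1 (adjusted p = 0.222) or genes that free RNA could carry (adjusted p = 0.0892). With an estimated correlation MHC class I had an adjusted p = 0.632 and the other 3 lists an adjusted p = 0.515. None of the 16 T cell effector and exhaustion genes passed (camera's adjusted p = 0.895): the log2 fold change was 2.24 ± 0.53 for Prf1, the perforin gene (adjusted p = 0.0696), and −1.67 ± 0.45 for Cd4 (adjusted p = 0.0913). Of 12709 genes, 397 passed, 239 higher and 158 lower. With edgeR none passed in a fit of the 4 nuclei libraries (2004 at an unadjusted p under 0.05), without engrafted replicate 1 (2480) or 2 (2720) or at 1000 genes per barcode (1785), 233 passed without de novo replicate 2, and DESeq2 on all 6 passed 896.

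Macrophage-like and microglia-like nuclei pooled differed between tumour types in cell cycle genes and in single genes such as Mmp12, in a contrast of de novo nuclei named mainly microglia-like with engrafted ones named macrophage-like. Mmp12, a macrophage elastase, had 23.8 ± 3.20 CPM in engrafted nuclei and no UMI in de novo ones, at least 43.9-fold higher (adjusted p = 0.0288). The lectin receptor Clec4n rose by 5.88 ± 0.56 on the log2 scale, the integrin Itgax by 3.16 ± 0.44 (15 ± 1.22 to 135 ± 10.2 CPM), Il1b by 4.13 ± 0.63, the monocyte chemokine receptor Ccr2 by 2.39 ± 0.54, the inhibitory receptor Lilrb4a by 2.12 ± 0.46 and Tgfbi by 5.00 ± 0.82; Ccr2 and Tgfbi are among the macrophage markers. The proton pump subunit Atp6v0d2 had 106 counts against 3, a ratio of 64.9 (counting interval 22.2 to 315). The microglial genes P2ry12 (−1.69 ± 0.42, adjusted p = 0.0598) and Siglech (−4.27 ± 1.12, adjusted p = 0.0673) were lower without passing. Of 28 cell cycle genes 18 rose, and 27 adjusted over the list alone (camera's adjusted p of the list, 1.02e-19), with Mki67 at 2.82 ± 0.39 (adjusted p = 0.035 for the gene). Of 20 interferon response genes 3 rose, and 7 adjusted over the list alone (camera's adjusted p of the list, 7.38e-07), with Ifi44 at 2.28 ± 0.37 (adjusted p = 0.0374 for the gene). Both lists had an adjusted p = 0.445 with an estimated correlation. The dissociation and immediate early list passed too, with 2 of 18 genes higher, also adjusted over the list alone (adjusted p = 0.0151; adjusted p = 0.445 with an estimated correlation; adjusted p = 0.138 without de novo replicate 2). Handling could thus not be set apart from the other changes. Transcripts of other cells moved here as well: 8 OPC programme genes rose and 1 fell of 16 (12 and 2 adjusted over the list alone, adjusted p = 2.23e-09, adjusted p = 0.158 with an estimated correlation), with Vcan at 3.52 ± 0.36, 9 of 20 neuronal genes fell (17 adjusted over the list alone, adjusted p = 9.92e-16, adjusted p = 0.445 with an estimated correlation), with Gabra6 at least 226-fold lower, and Akaluc was at 19.3 and 61.0 CPM in engrafted macrophage-like nuclei. In all 853 of 13524 genes passed, 303 higher and 550 lower. With edgeR none passed in a fit of the 4 nuclei libraries (2621 at an unadjusted p under 0.05), without de novo replicate 2 (2507) or without engrafted replicate 2 (3089), 537 passed without engrafted replicate 1, and DESeq2 on all 6 passed 1819.

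Within the 3 libraries that held both myeloid classes (de novo nuclei replicate 1 and both engrafted cells libraries), macrophage-like barcodes had more MHC class II and less homeostatic microglia RNA than microglia-like ones. Class markers were left out, ratios were taken with 1 CPM added, and no test was run because the classes were defined from the same values. The mean log2 ratio over 9 MHC class II genes was 0.81 ± 0.49 (SD, n = 3), above 0 in 3 of 3 libraries but −0.10 in engrafted nuclei replicate 1, which held both classes at resolution 2, with H2-Ab1 at 1.55 ± 0.55, H2-Eb1 at 1.46 ± 0.52 and Ciita at 1.40 ± 0.39, while H2-Oa, which restrains peptide loading, was at −1.53 ± 0.79. The 4 remaining homeostatic genes averaged −1.31 ± 0.19, with Fcrls at −2.29 ± 1.40 and P2ry13 at −1.55 ± 0.39. The mesenchymal programme averaged 0.81 ± 0.35 and the dissociation and immediate early list 0.51 ± 0.50, each above 0 in 3 of 3 libraries. The checkpoint list averaged 0.33 ± 0.09, led by Il10 (2.40 ± 0.29) and Pdcd1lg2, the PD-L2 gene (2.26 ± 0.49). Disease-associated microglia genes averaged −0.57 ± 0.94 and were split by preparation, 0.50 in de novo nuclei against −0.97 and −1.25 in engrafted cells, with Cst7 (−4.57 ± 0.54) and Csf1 (−2.92 ± 1.29) higher in microglia-like and Lgals3 (1.41 ± 0.81) and Apoe (0.94 ± 0.80) higher in macrophage-like barcodes.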

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

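The tests of whether neuron transcripts came from free RNA or from the OPC-like nuclei themselves, and of whether the naming or the clustering hides microglia-like nuclei, were chosen only after the result was seen. The test of free RNA hiding microglia genes was set beforehand.

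Y-linked genes reached 391.0 CPM in de novo nuclei replicate 1, a library labelled female, with Xist at 0.414 CPM; every class named in it carried them, OPC-like nuclei at 467 and T/NK-like nuclei at 486 CPM. The de novo libraries thus differed in sex-linked RNA, and the comparison of engrafted with de novo nuclei includes that difference. GFP stood at 18.9 CPM in OPC-like nuclei of de novo replicate 1 and at 100.0 CPM in those of replicate 2, above the engrafted nuclei, although Akaluc there was at 2.99 and 0.443 CPM and tagged H3.3 at 0 and 0.554 CPM. Akaluc stood at 26.3 CPM in T/NK-like nuclei of engrafted replicate 1 and 53.6 CPM in those of replicate 2, cells that should not carry the construct, against 6.19 and 3.63 CPM in T/NK-like engrafted cells.

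Cerebellar neuron genes such as Gabra6, Pcp2 and Cbln3 were lower in engrafted nuclei in OPC-like, T/NK-like and pooled myeloid nuclei alike. Over 21 such genes the median ratio of the OPC-like to the T/NK-like level was 0.648 in de novo replicate 1 and 0.727 in replicate 2. That lay on the side set as arguing against expression by the OPC-like nuclei themselves. The 21 genes were those named as lower in OPC-like, T/NK-like or pooled myeloid nuclei. Some were thus picked for their level in de novo T/NK-like nuclei, so the ratio cannot decide. Free RNA from neurons in the de novo suspensions may account for these genes, and the median of the largest over the smallest class level was 1.46 in de novo replicate 2. It was 2.45 in replicate 1, between the bounds set for and against, and there Nrg3os stood at 176 CPM in OPC-like and 2.61 CPM in T/NK-like nuclei, so free RNA cannot be told apart from class-specific expression for part of the genes. In neuron-like nuclei of engrafted replicates 1 and 2, Gabra6 stood at 0.523 and 0 CPM and Pcp2 at 0.314 and 0 CPM. Those of de novo replicates 1 and 2 had 124 and 463 CPM of Gabra6 and 28.6 and 122 CPM of Pcp2. Mir124a-1hg, another of the 21 genes, still stood at 107 and 116 CPM in the engrafted neuron-like nuclei. A larger amount of cerebellum in the de novo dissections goes with those values. It stays open as the origin of the cerebellar RNA and was not tested.

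Nuclei named macrophage-like stood in place of microglia-like ones in engrafted tumours. The naming rule fits as an explanation, since microglia markers summed over all barcodes kept a median of 0.735 of their de novo level, and the ratio was 1.03 between engrafted replicate 1 and de novo replicate 2 but 0.409 between engrafted replicate 2 and de novo replicate 1. Clustering cannot be told apart from it: the lowest macrophage-like share of named myeloid nuclei in an engrafted library was 73.0% (325 of 445 nuclei of replicate 1, at resolution 2), but every setting used the same rule. Free RNA hiding the microglia genes cannot be told apart from their absence either, as macrophage markers were only 1.7-fold over their T/NK-like level in pooled myeloid nuclei of engrafted replicate 2 and 3.12-fold in replicate 1, a weakness shared with de novo nuclei (2.13 and 1.07). A different recruitment of myeloid cells by engrafted tumours remains an open, untested hypothesis, as do the dissected region and the host.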

How the results depend on the processing

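The comparisons of T/NK-like and of pooled myeloid nuclei, list tests between preparations, sums of OPC-like with committed precursors and the crossed block were chosen only after the data were seen. Counts of changed genes follow for OPC-like, T/NK-like and pooled myeloid nuclei between tumour types (954, 397 and 853), in that order. They were 3079, 896 and 1819 with DESeq2, 2022, 1903 and 2797 without the filter on low counts, 2051, 1229 and 535 with doublets kept, and 400, 188 and 486 at equal depth. Each was 0 with edgeR on the 4 compared libraries (3357, 2004 and 2621 at an unadjusted p under 0.05), where the lowest adjusted p of a named gene was 0.0691, 0.0775 and 0.0616. That fit leaves out the engrafted cells, which varied least (in OPC-like sums a coefficient of variation of 0.221, against 0.463 in de novo and 0.515 in engrafted nuclei). At 1000 genes per barcode 487 OPC-like and 0 T/NK-like genes passed (1785 at an unadjusted p under 0.05). With each library left out in turn the counts ranged from 88 to 1016, 0 to 554 and 0 to 1128. The lowest were without engrafted replicate 2 (88, 0 and 0), while without engrafted replicate 1 they were 268, 0 and 537 and without de novo replicate 2 they were 358, 233 and 0; each zero had 2480 or more at an unadjusted p under 0.05. A lone library was assumed to vary like the other groups.

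Between preparations, 5822 of 10216 OPC-like and 2069 of 5667 macrophage-like genes passed at equal depth. Left-out libraries gave 5970 to 9664 and 1556 to 8213, lowest without either engrafted cells library (5970 and 6080; 1723 and 1556). All 13 named OPC-like genes passed under each of the 8 refits. Between tumour types, 27 of 30 named OPC-like genes passed, and 3 of them lost their call with DESeq2's size factors, 7 with the block, and 9, 16, 17 and 18 without de novo replicate 1 or 2 or engrafted replicate 1 or 2. No named gene that passed changed direction under the 8 refits run for named genes. Among named OPC-like genes that did not pass, 1 changed direction without de novo replicate 1 and 1 without engrafted replicate 2.

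No list passed in any of the 5 comparisons with an estimated correlation (0; 2, 2, 1, 2 and 2 lists at an unadjusted p under 0.05). Under the free RNA guard, which evenly spread RNA passes, 4 of 7 lists passed in OPC-like nuclei and 4 of 9 between preparations. Of these lists, 1 and 4 had fewer than 3 genes left and were not tested. Fry passed 1 of 7 lists in T/NK-like and 2 of 14 in pooled myeloid nuclei. In OPC-like nuclei it passed cell cycle, both MHC, astrocyte and neuronal lists (fry's adjusted p = 0.0383 each). Interferon response (0.263) and oligodendrocyte maturation (0.429) were lost. Between preparations it lost cell cycle (0.0628), cytokines (0.065) and neuronal genes (0.065) in OPC-like barcodes, and only neuronal genes (0.141) in macrophage-like ones.

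Replicate numbers did not pair the libraries: deviations of same-numbered OPC-like libraries correlated at 0.066, 0.005 and −0.111. A replicate block gave 463, 235 and 563 genes between tumour types, and with crossed numbers 9952 OPC-like genes between preparations.

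The log2 ratio of microglia-like shares was −8.45 and became −2.90 with doublets kept, −7.51 at 1000 genes and −2.72 at resolution 2; left-out libraries gave −8.63 to −7.10. Those of macrophage-like and OPC-like shares ranged from 2.57 to 8.24 and from 1.22 to 4.70, the extremes being without a de novo library. The macrophage-like excess among myeloid nuclei was 79.6 points at resolution 2. At resolution 2 engrafted nuclei replicate 1 also held both myeloid classes, with a log2 macrophage-to-microglia ratio of −0.10 for MHC class II (mean 0.58 ± 0.59, above 0 in 3 of 4 libraries). In nuclei alone the ratio was 1.35 for MHC class II and, of opposite sign to the mean, 0.50 for disease-associated microglia genes; only 1 library remains. Except where a setting leaves fewer libraries or reads, the cause was not tested.

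On simulated counts for OPC-like nuclei, edgeR recovered 1.5%, 19.4% and 74.2% of genes changed 2-, 4- and 16-fold, and 16 of 81 calls were false (17752 genes), so small changes were not detectable. Not run, for want of 50 barcodes in a library, were microglia-like contrasts, macrophage-like contrasts between tumour types, the test of a differing response, and their lists.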

Other observations

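The comparison of pooled myeloid nuclei and its list tests were chosen only after the data were seen, and the pattern of genes without nuclear UMIs was itself found in these data.

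Other lists moved in the pooled myeloid nuclei of engrafted tumours. Of 18 mesenchymal genes 4 rose, and 9 rose and 1 fell adjusted over the list alone (camera's adjusted p = 0.000344). No MHC class I gene passed over all genes with edgeR, but 6 of 12 rose adjusted over the list alone and the list passed (adjusted p = 3.29e-05), as did lipid handling, with 15 of 16 genes above 0 and none passing alone (adjusted p = 0.00726). With an estimated correlation each of these had an adjusted p = 0.445. MHC class II passed with no gene past the threshold over all genes or over the list alone (adjusted p = 0.00176; adjusted p = 0.48 with an estimated correlation). Inflammatory cytokines passed with 1 of 17 genes higher and 3 adjusted over the list alone (adjusted p = 0.0175; adjusted p = 0.49 with an estimated correlation), but not without de novo replicate 2 (adjusted p = 0.166) or engrafted replicate 2 (adjusted p = 0.204). Tumour model genes passed with 1 of 4 higher, also over the list alone (adjusted p = 0.0273; adjusted p = 0.445 with an estimated correlation), but with any of the 4 nuclei libraries left out had an adjusted p of 0.0586 or more. One gene each passed among disease-associated microglia genes (Itgax, list adjusted p = 0.00586) and checkpoint genes (Lilrb4a, list adjusted p = 0.00726), and with an estimated correlation these had an adjusted p = 0.49 and an adjusted p = 0.48. Without de novo replicate 2 they had adjusted p of 0.0966 and 0.082, and without engrafted replicate 1 the checkpoint list had 0.0592. Homeostatic microglia genes were lower as a list (adjusted p = 0.00742; adjusted p = 0.605 with an estimated correlation), though 9 of the 13 tested are class markers and none passed alone with edgeR, 4 doing so adjusted over the list alone, and the list had an adjusted p of 0.563 without de novo replicate 1.

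Cytokine genes also split the 2 myeloid classes within the libraries that held both. Il1a was higher in microglia-like barcodes (log2 ratio −3.85 ± 1.08, SD, n = 3) and Il12b in macrophage-like ones (2.26 ± 1.06), while the list as a whole averaged 0.01 ± 0.27. Cd9 (−1.51 ± 0.91) and the lysosomal protease gene Ctsd (−1.88 ± 1.82) were higher in microglia-like barcodes on average, and Ctsd stood at 8241 CPM in microglia-like against 1033 CPM in macrophage-like barcodes of engrafted cells replicate 1 but at 387 against 451 CPM in de novo nuclei replicate 1.

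Of 6093 genes with at least 20 CPM in engrafted cells, 64 had no UMI in any of the 4 nuclei libraries, among them Cox4i1, Irf8, Tubb3 and Chchd2. A candidate explanation is that whole-gene counting of nuclei discarded reads where gene spans overlap on the same strand: 96.9% of the 64 (62 genes) overlapped another gene of their strand, against 3.4% of the other 6029 (207 genes) and 3.3% of genes matched on abundance (Fisher's exact p = 1.20e-84). Cox4i1, Irf8 and Tubb3 lie inside the span of Gm20388 on chromosome 8. Transcripts confined to the cytoplasm were argued against, since 100.0% of the respiration genes with no such overlap (80 of 80) had UMIs in the nuclei. Overlap was not enough by itself, as 207 overlapping genes of that abundance did have UMIs in the nuclei.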
